A study of Mus musculus with 9 samples.

How the data were processed

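RNA of the anterior prostate was hybridised to Affymetrix arrays, 3 arrays for each of 3 genotypes. The deposited values are log2 signals; RMA is the only tool the submitters' processing notes name, with no version, and the log2 scale follows from the values, which run from 2.31 to 14.02. RMA corrects background, quantile-normalises the arrays and summarises the probes of a set, so values of different arrays are on a common scale as deposited. The deposited table is a selection of probe sets, and no label states its rule. The values show 3525 probe sets that all have a Pten-Lrf deletion mean at least 1.5-fold above the wild-type mean, the smallest log2 difference being 0.59. The count of Pten-Lrf deletion against wild-type is therefore one-sided, and genes lower there than in wild-type are missing from every comparison. Normalising or centring this table again forces a balance that a full array would have but a selected table does not. Scanner files were not analysed here.

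Probe sets were named through the platform annotation given with the series, with symbols brought up to date by Entrez gene number, which matched for all 2825 probe sets with 1 symbol. A further 32 probe sets had several symbols, 664 were not listed in that annotation, and 4 were control probe sets. Unlisted and multi-gene probe sets stay unnamed. The probe set with the highest mean over the 9 arrays stood for each of the 2173 genes, 504 of which had more than 1. Of the named genes, 16, 2 and 19 had another probe set in the 3 comparisons in the order given below. One of these, Sox9 in Pten-Lrf deletion against Pten deletion, had a second set of opposite sign, and 1 gene in Pten deletion against wild-type had a set on the other side of the threshold.

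All 9 arrays entered 1 limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with a mean per genotype, so that the genotypes shared an estimate of the spread per gene. The 3 comparisons were Pten deletion against wild-type, Pten-Lrf deletion against Pten deletion, and Pten-Lrf deletion against wild-type. Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 over all genes. The fit was tested on simulated data of 2173 genes with known changes: for the comparison of the 2 deletion genotypes it recovered 50% of changes of 1 log2 unit and 87% of changes of 2, for Pten deletion against wild-type 67% and 88%, and for Pten-Lrf deletion against wild-type 62% and 89%. The simulation drew genes independently, with 1 spread per gene for all genotypes. The real Pten deletion arrays spread more than the others, so these shares do not give the recovery in the real comparisons.

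Design, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The SOX9 and cartilage, neutrophil and chemokine lists were chosen knowing what was published on this model, so they are not independent evidence. The rule took, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups of 3 arrays did not overlap, the 3 largest changes of each list with at least 2 genes past the threshold, and a set of fixed genes, of which Sox9, Mia, Cxcl5, Cxcl17 and Cdkn1a were in the table. The 9 others, H19, Fbn2, Col2a1, Cdkn2a, Trp53, Mki67, Nkx3-1, Ar and Pbsn, were not analysed here. Of 28 gene lists 22 had a gene in the table. The 6 without any were seminal vesicle, smooth muscle, skeletal muscle, adipocyte, blood and endoplasmic reticulum stress genes. The 14 lists with at least 5 measured genes were tested with camera at an inter-gene correlation of 0.01, adjusted over 42 list and comparison pairs; 10 pairs passed, and 0 with an estimated correlation, where the lowest adjusted p was 0.822. Counts adjusted over the list alone use the members of that list as the only tests. Overlaps were set beside 100 simulated draws of unchanged groups against the same arrays and beside the overlap of independent lists.

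Alternatives were quantile normalisation and median centring of the table, a filter that left out the lowest 0.25 of genes by mean, other treatments of several probe sets per gene, a fit with only the 2 genotypes compared, trend and robust moderation, array weights (statmod 1.5.0), a replicate block, leaving out each array in turn, a minimum log2 fold change of 1, an adjusted p under 0.01, and, for lists, an estimated correlation and fry. After the data were seen, a fit on rows selected alike for both deletion groups and a fit with the Gapdh 5' to 3' difference as a covariate were added. An exact two-sided permutation test of that difference between 3 and 3 arrays cannot give a p under 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Arrays give no read depth, and their number limits the precision.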

Results

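Transcript levels were measured with Affymetrix arrays in the anterior prostate of C57BL/6 mice aged 12 weeks. The 9 arrays fell into 3 genotypes of 3 arrays each: wild-type, deletion of Pten in the prostate epithelium (Pten deletion), and deletion of Pten together with Lrf (Pten-Lrf deletion). Pten encodes a lipid phosphatase that opposes PI 3-kinase signalling. Lrf is the zinc-finger transcription factor encoded by Zbtb7a. The question behind the design was which transcripts go with loss of Lrf on top of Pten. The sample titles name all 6 deletion samples as anterior prostate tumours. The table analysed holds 3525 probe sets on the log2 scale, and 2825 of them carry 1 gene symbol and stand for 2173 genes. In all 3525 probe sets the Pten-Lrf deletion mean lay at least 1.5-fold above the wild-type mean, so genes lower in Pten-Lrf deletion than in wild-type are not part of these data. Pten and Zbtb7a were not analysed here, because neither has a named probe set in the table, and the genotype labels have no check from the targeted genes.

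The mean log2 value over the 3525 probe sets was 6.53 ± 0.09 in wild-type, 7.89 ± 0.31 in Pten deletion and 8.30 ± 0.09 in Pten-Lrf deletion (SD, n = 3 arrays each). The Pten deletion arrays differed most among themselves, with means of 8.24, 7.77 and 7.65. The median SD of a gene over 3 arrays was 0.43 in Pten deletion, 0.17 in wild-type and 0.16 in Pten-Lrf deletion. Every SE below pools the 3 genotypes, as do the p-values of fits to all arrays. They do not measure the spread of the 2 groups compared alone. For a typical gene they understate the spread of Pten deletion and overstate that of the other genotypes. The difference between the 5' and 3' Gapdh control probe sets, a measure of RNA integrity, was -0.86 ± 0.09 in wild-type, -0.85 ± 0.25 in Pten deletion and -0.43 ± 0.13 in Pten-Lrf deletion. The number of arrays limits the precision of every value below.

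In Pten deletion against wild-type, which asks how tumours with loss of Pten alone differ from the gland, the 8 largest rises were the following. Wfdc18, a secreted whey acidic protein family member, rose 395-fold, from a log2 value of 3.91 ± 0.15 to 12.54 ± 0.37 (log2 fold change 8.63, SE 0.23, limma adjusted p = 5.0e-08). Tff3, a trefoil factor of mucous epithelia, rose by 7.84 (SE 0.34), Dmbt1, a mucosal scavenger receptor, by 6.95 (SE 0.20), and Pglyrp1, a peptidoglycan recognition protein, by 6.82 (SE 0.51). The epithelial marker Wfdc2 rose by 6.72 (SE 0.52) and Lypd8, a glycoprotein of gut epithelium, by 6.32 (SE 1.16), where the SD among the 3 Pten deletion arrays was 3.00. Ifit1bl1 and Ubd, both known as interferon-inducible, rose by 6.31 (SE 0.63) and 5.99 (SE 0.81).

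All 14 measured interferon-response genes rose in Pten deletion, with a median log2 fold change of 3.99, among them Ifit1 (5.59, SE 0.46), Oasl2 (4.91, SE 0.41) and Usp18 (4.87, SE 0.49). The list stood above the other genes of the table by camera with a preset correlation (adjusted p = 0.00092), and not with an estimated correlation (adjusted p = 0.954). The interferon list was highest in Pten deletion array 1, whose median lay 5.14 above wild-type, against 3.06 and 3.49 in arrays 2 and 3. Of 12 luminal and luminal-progenitor epithelial markers 11 rose, with a median of 2.56 (camera adjusted p = 0.0026, and adjusted p = 0.822 with an estimated correlation), but 4 of the 12 were lower with each array centred (median 1.29) or after quantile normalisation (median 1.22). The 11 included Ly6d at 5.56 (SE 0.52) and the keratin Krt4 at 5.55 (SE 0.25). Of 7 basal markers 6 rose (camera adjusted p = 0.061), with Krt15 at 3.19 (SE 0.23), Col17a1 at 3.03 (SE 0.34) and Krt5 at 1.96 (SE 0.17).

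Immune and stromal lists are given here beside all 2173 genes, of which 1743 rose, with a median log2 fold change of 1.03. That median was -0.24 with each array centred and -0.29 after quantile normalisation, so the rises of these lists include the table-wide one. All 14 macrophage and myeloid markers rose (median 2.53, camera adjusted p = 0.0072, and adjusted p = 0.954 with an estimated correlation), led by Arg1 at 4.24 (SE 0.42) and Ms4a7 at 3.09 (SE 0.30). The list did not pass by camera without Pten deletion array 1 (adjusted p = 0.065), although its median above that of all genes was not smaller, 1.62 against 1.51 with all arrays. All 4 MHC class II genes rose, with H2-Ab1 at 2.24 (SE 0.34) and H2-Aa at 2.17 (SE 0.31). Of 17 chemokine and cytokine genes 15 rose (camera adjusted p = 0.611), with Ccl8 at 4.86 (SE 0.64), Cxcl10 at 3.13 (SE 0.60) and the neutrophil attractant Cxcl5 at 2.89 (SE 0.74). Cxcl17, a mucosal chemokine, rose by 3.12 (SE 0.39). All 11 fibroblast and extracellular matrix genes rose (median 2.70, camera adjusted p = 0.197, and adjusted p = 0.987 with an estimated correlation), including Tnc at 3.85 (SE 0.65), Timp1 at 3.62 (SE 0.65) and Thbs2 at 3.25 (SE 0.63). A second probe set rose by only 0.45 for Tnc and by 1.64 for Thbs2. The medians of the fibroblast and macrophage lists were highest in Pten deletion array 2, at 4.06 and 3.24 above wild-type, against 2.22 and 2.49 in array 1 and 1.84 and 1.77 in array 3. Of the 4 neutrophil markers in the table, from 24 listed, 1 rose, Ltf. Of 10 genes of epithelial-mesenchymal transition and invasion 7 rose (camera adjusted p = 0.795), with Mmp3 at 3.22 (SE 0.66) and Itgb6 at 2.56 (SE 0.41). The median of that list, 1.73, was 0.46 under centring and 0.17 after quantile normalisation, with 4 of the 10 genes lower either way.

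The p53 target, cell-cycle, glycolysis, cholesterol and FOXO lists did not pass by camera in Pten deletion (adjusted p = 0.059, 0.175, 0.070, 0.271 and 0.975). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 8.74-fold (log2 fold change 3.13, SE 0.28), Cdkn2b rose by 2.91 (SE 0.40), and 6 of 7 p53 targets and kinase inhibitors rose. Of 32 cell-cycle and E2F-target genes 31 rose, with Birc5 at 2.38 (SE 0.41) and Ccnb2 at 2.11 (SE 0.24), but their median of 1.19 was near that of all genes in the table, 1.03, and it turned to -0.08 with each array centred on its median. All 10 glycolysis genes rose, and Hk2, the inducible hexokinase, led them at 3.93 (SE 0.21); the median of the list, 1.11, turned to -0.16 under centring. Of 9 cholesterol and fatty acid synthesis genes 7 rose, with Cyp51 at 1.53 (SE 0.23), and of 7 FOXO targets 6 rose, with Gadd45a at 2.33 (SE 0.33) and Cat at 1.59 (SE 0.19). The medians of these lists, 0.70 and 0.96, turned to -0.57 and -0.31 under centring. All 8 measured immediate early genes rose, with Fos at 2.68 (SE 0.42). Of 5 measured androgen-responsive genes 4 rose, with Steap4 at 2.54 (SE 0.51) and Homer2 at 2.06 (SE 0.30). By camera neither list passed (adjusted p = 0.059 and 0.967). Counts here cover only list members in a table of genes raised in Pten-Lrf deletion. These were 8 of 17 listed immediate early, 5 of 18 androgen-responsive and 7 of 28 p53 genes. For cell-cycle genes they were 32 of 50, for glycolysis 10 of 20, for cholesterol 9 of 22 and for FOXO 7 of 18. The median of the immediate early list, 1.67, was 0.40 under centring and 0.42 after quantile normalisation, and that of the androgen-responsive list, 1.41, was 0.14 and 0.18, with 2 of its 5 genes lower in Pten deletion either way. Sox9, a progenitor transcription factor, rose by 1.77 (SE 0.28), but by 0.48 after quantile normalisation and 0.50 under centring, where it did not pass (limma adjusted p = 0.20 and 0.19). Mia, a secreted protein of cartilage and melanoma, rose by 1.55 (SE 0.24), though it stood at -0.067 after quantile normalisation. Col11a1, the third measured member of the SOX9 and cartilage list, rose too. Of the 2 measured prostate secretory products 1 rose, Sbp. The only T cell marker in the table, Thy1, rose, and the single endothelial, nerve and plasma cell genes (Flt1, Mal and Jchain) did not pass.

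By limma, 1743 of 2173 genes rose and 0 fell at an adjusted p under 0.05 (1790 rose and 0 fell at an unadjusted p under 0.05), and 1090 of these rises were at least 2-fold. The 2 groups of arrays did not overlap in 81.9% of genes; chance gives 10% with rows not selected. Rows were chosen for being high in Pten-Lrf deletion, so genes lower there than in wild-type are missing from this count. The selection seen in the values uses the wild-type mean but not the Pten deletion arrays. How far it shapes the count in Pten deletion was not tested. With the table quantile-normalised the count was 384 rises and 808 falls, and with each array centred 440 and 779.

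**Figure D1:**
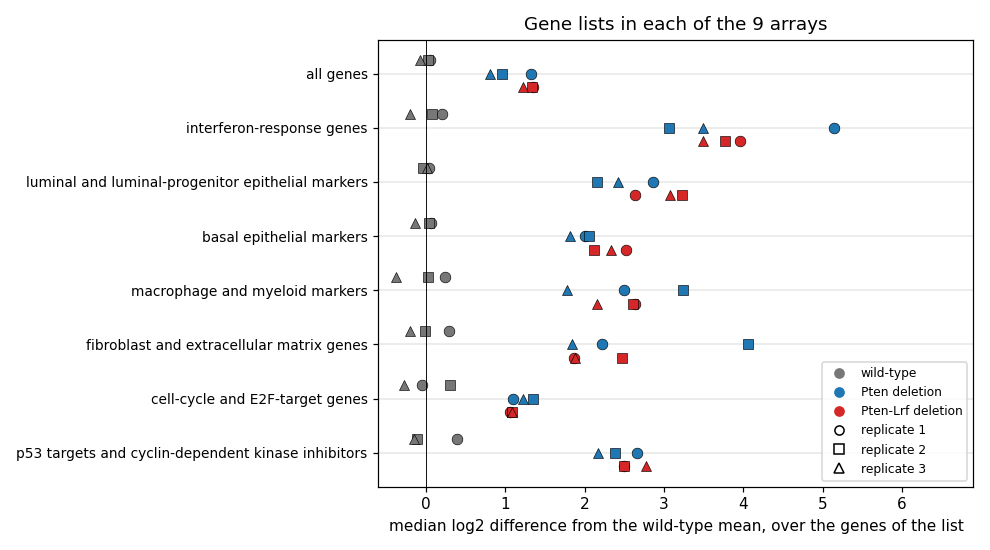
Median log2 difference from the wild-type mean (horizontal axis) over the genes of 8 sets (vertical axis) in each of the 9 arrays, coloured by genotype, with a marker shape per replicate number. Pten deletion array 1 has the highest interferon median (5.14) and array 2 the highest fibroblast median (4.06).

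Pten-Lrf deletion against Pten deletion asks what loss of Lrf adds. Mia rose 20.3-fold, from 6.41 ± 0.33 to 10.75 ± 0.16 (log2 fold change 4.34, SE 0.24, limma adjusted p = 4.8e-05, n = 3 arrays each). Spink1, a trypsin inhibitor secreted by several glands, showed the largest difference, 64.4-fold (6.01, SE 0.71, adjusted p = 0.0057), and Krt20, a keratin of gut and urothelium, rose 15.5-fold (3.95, SE 0.44, adjusted p = 0.0041). Cxcl5 rose 16.8-fold, from 6.21 ± 1.73 to 10.28 ± 0.69 (4.07, SE 0.74, adjusted p = 0.038). Reg1 (4.77, SE 0.91), the carbonic anhydrase gene Car9 (3.87, SE 0.66), Sptssb, a subunit gene of serine palmitoyltransferase (3.57, SE 0.52), and Ivl, which encodes involucrin of the cornified envelope (3.20, SE 0.69), completed the 8 largest rises. Wfdc18, which had shown the largest rise with Pten deletion, was the 1 gene that fell, by 1.08 (SE 0.23, adjusted p = 0.047).

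Sox9 and Cdkn1a, both raised by Pten deletion, differed little between the deletion genotypes. Sox9 was 8.24 ± 0.13 in Pten-Lrf deletion and 8.10 ± 0.52 in Pten deletion (adjusted p = 0.77), with a second Sox9 probe set at -0.17, and Cdkn1a was 9.64 ± 0.25 and 9.47 ± 0.11 (adjusted p = 0.71). Both differences were below 0 after quantile normalisation or centring. Cxcl17 was 1.68 (SE 0.39) higher in Pten-Lrf deletion and did not pass (adjusted p = 0.071).

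Of 24 listed neutrophil markers 4 were in the table. None of the 4 passed over all genes, and all 4 passed adjusted over the list alone. S100a8 was 3.72 higher in Pten-Lrf deletion, S100a9 3.64, Ltf 2.10 and Il1b 2.05. Of 17 chemokine and cytokine genes only Cxcl5 passed over all genes, and 5 passed adjusted over the list alone. Of the prostate secretory products Spink1 passed and Sbp, 3.68 higher, did not, while both passed adjusted over the list alone. Of the basal markers Lgals7 rose (1.69, SE 0.33), and 2 of 7 passed adjusted over the list alone. The same adjustment passed 3 of 10 epithelial-mesenchymal transition genes, 1 of 5 androgen-responsive genes, 1 of 7 FOXO targets, the nerve marker Mal, and Mia of the 3 SOX9 and cartilage genes. Mal was the only measured nerve marker, so its p stayed unadjusted. By limma 507 of all 2173 genes had an unadjusted p under 0.05, with 492 of them higher in Pten-Lrf deletion. Counts adjusted over a list alone are to be read beside that share. By camera the chemokine, basal, epithelial-mesenchymal transition, androgen-responsive and FOXO lists did not pass (adjusted p = 0.967, 0.961, 0.955, 0.967 and 0.967). No luminal marker passed, although all 12 had a higher mean in Pten-Lrf deletion (median 0.65; 8 of 12 and 0.25 with each array centred).

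None of 32 cell-cycle genes (median -0.15), 11 fibroblast genes (-0.43), 14 macrophage markers (-0.19) and 14 interferon-response genes (0.07) passed, whereas the median of all genes was 0.29. With each array centred these medians were -0.55, -0.83, -0.60 and -0.33 beside -0.11 for all genes, and after quantile normalisation -0.71, -0.68, -0.53 and -0.28 beside -0.08; the 32 cell-cycle and 11 fibroblast genes then all had lower means in Pten-Lrf deletion. By camera with a preset correlation these lists lay below the other genes of the table, with adjusted p of 5.5e-10, 1.8e-05, 0.00025 and 0.0086. None did with an estimated correlation (adjusted p = 0.822 for the first 3 lists and 0.954 for the interferon list), and after quantile normalisation the fibroblast and interferon lists did not pass with the preset one (adjusted p = 0.071 and 0.27). Without Pten deletion array 2 the fibroblast and macrophage lists no longer differed from the other genes (adjusted p = 0.563 and 0.488), and without array 1 the interferon list lay 0.12 above them (adjusted p = 0.991); without Pten-Lrf deletion array 3 its adjusted p was 0.063. All 4 MHC class II genes had lower means in Pten-Lrf deletion (median -0.57), with 0 passing. No member of the p53 target, glycolysis, cholesterol or immediate early lists passed, with medians between 0.17 and 0.35 that were all negative with each array centred.

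By limma, 49 genes rose and 1 fell, and 45 of the rises were at least 2-fold. At an unadjusted p under 0.05 the numbers were 492 and 15, and the groups did not overlap in 22.5% of genes; chance gives 10% with rows not selected, and the row selection by itself raises that share. Quantile normalisation gave 27 calls, 23 up and 4 down, and 23 of the 27 were among the 50. The count depended on single arrays: it was 884 without Pten deletion array 1, 21 without array 2, 12 without array 3, and 9 to 14 without any 1 of the 6 wild-type and Pten-Lrf deletion arrays. The 6 genes called in each of these 9 fits were Mia, Spink1, Krt20, Dmbt1, Upk1a and Apoc1, the last 3 named after their values were seen. Sptssb was called in 6 of the 9 fits, Cxcl5 in 2, and Reg1, Car9, Ivl and Wfdc18 in 1 each. With the Gapdh 5' to 3' difference as a covariate, a check chosen after the data were seen, 2 calls were left, Mia at 4.34 (SE 0.39) and Dmbt1 at 2.59 (SE 0.26). All 50 kept their direction, with a median of 80.0% of the log2 fold change and of 140% of the SE: Spink1 was at 7.28 (SE 1.05), Krt20 at 3.35 (SE 0.68) and Cxcl5 at 3.42 (SE 1.21), while Car9 fell to 2.31 (SE 0.86), Reg1 to 2.39 (SE 1.10), Sptssb to 2.03 (SE 0.52) and Ivl to 1.54 (SE 0.88).

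**Figure D2:**
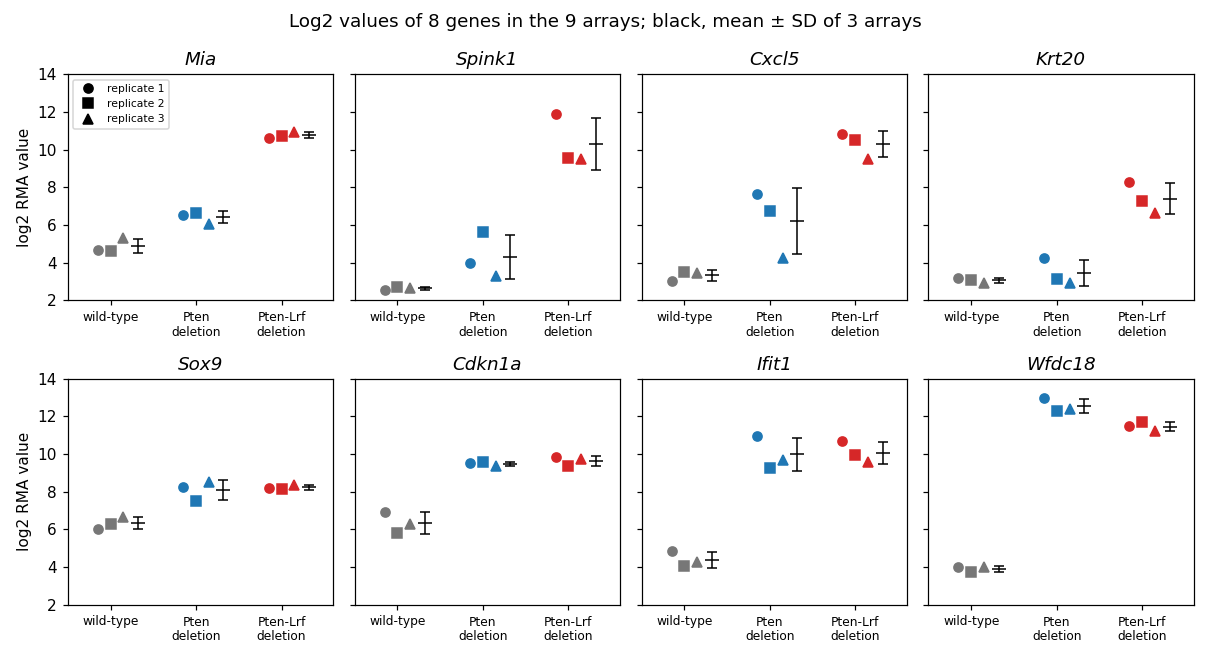
Log2 RMA values (vertical axis) of 8 genes in the 9 arrays by genotype (horizontal axis), 1 point per array, with the mean ± SD of 3 arrays in black. Mia and Krt20 are separated in Pten-Lrf deletion from the other genotypes, while Sox9, Cdkn1a and Ifit1 lie at similar levels in both deletion genotypes and above wild-type.

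Pten-Lrf deletion against wild-type gives the size of the combined change. Lypd8 was 10.07 higher on the log2 scale, reaching 13.26 ± 0.07 from 3.20 ± 0.17. Its SE of 1.16 takes in the wide spread of the Pten deletion arrays, which are not compared here. Dmbt1 was 9.86 higher (SE 0.20). The antimicrobial lectins Reg3b (9.39, SE 1.39) and Reg3g (8.42, SE 0.91) followed, with Wfdc2 (256-fold), the iron-binding lactoferrin gene Ltf (7.89, SE 0.73), Clca1, a secreted regulator of chloride channels (7.80, SE 0.97), and Spink1 (7.68, SE 0.71). Mia was 59.2-fold higher (5.89, SE 0.24) and Cxcl5 124-fold (6.96, SE 0.74). S100a8 was 5.74 higher (SE 0.93), S100a9 5.52 (SE 0.94), Cxcl17 4.80 (SE 0.39), Cdkn1a 3.30 (SE 0.28) and Sox9 1.91 (SE 0.28).

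Every measured member of all 22 lists with a gene in the table passed, as all 2173 genes did, because the rows were selected for this difference; no p-value here is an independent test of a rise. The median was 5.63 for neutrophil markers, of which only 4 of 24 listed were in the table. It was 3.68 for interferon-response genes, 3.03 for luminal and 2.32 for basal epithelial markers. Chemokines had 2.99 and cell-cycle genes 1.02, beside 1.29 for all genes. With each array centred these medians were, in the same order, 3.96, 2.00, 1.35, 0.65, 1.31 and -0.66, beside -0.38 for all genes. The cell-cycle median was -0.84 after quantile normalisation, with all 32 genes lower than in wild-type. As deposited all 32 were at least 1.5-fold above wild-type, and normalising this selected table again forces a balance, so these falls are not a result. Luminal, basal and interferon lists stood above the other genes by camera with a preset correlation (adjusted p = 4.3e-05, 0.0076 and 0.014), and none did with an estimated one (adjusted p = 0.822, 0.822 and 0.954). By camera the basal list did not pass without Pten deletion array 1 (adjusted p = 0.098), nor the interferon list without Pten deletion array 3 (adjusted p = 0.086). These arrays enter this comparison only through the estimate of the spread. The list medians, 1.03 and 2.39 above that of all genes, do not depend on them. Of the 2173 rises 1412 were at least 2-fold, and quantile normalisation of the table gave 437 rises and 960 falls.

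The Pten deletion rise of a gene was 78.0% of its Pten-Lrf deletion rise at the median over genes, with quartiles of 60.2% and 94.7%. All 1743 genes that rose in Pten deletion also rose in Pten-Lrf deletion against wild-type. Independent lists of these sizes would overlap in 1743 as well and simulated unchanged groups in 0, so this overlap carries no information beyond the row selection, and both comparisons share the 3 wild-type arrays. Of the 49 genes that rose in Pten-Lrf deletion against Pten deletion, 27 had already risen with Pten deletion, among them Mia, Cxcl5, Car9, Ivl and Dmbt1, and 22 had not, among them Spink1, Reg1, Krt20 and Sptssb. Independent lists would share 39.3 genes, and the simulation gave 0. The Pten deletion arrays enter these 2 comparisons with opposite sign.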

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

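The tests of RNA integrity on Mia and the splits of arrays were chosen before their results were seen, and the other tests in this part after. Control probe sets, which the comparisons leave out, gave the first flagged values, with Pten-Lrf deletion above wild-type on the log2 scale. The 5' b-actin set was 0.71 higher, the 3' Gapdh set 1.16, the 5' Gapdh set 1.59 and the middle Gapdh set 1.44. Of the 696 probe sets without a single gene symbol, also outside the comparisons by gene, 14 rose in Pten-Lrf deletion against Pten deletion when probe sets were tested one by one.

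The control sets point to RNA quality as a first question. Loss of RNA integrity alone may shift 5' against 3' signal and leave the 3' Gapdh set in place; that set was 1.16 higher, but every row of the table was selected for this difference, so the value decides nothing there. The selection seen in the values does not use the Pten deletion arrays, but it does use the wild-type mean. In Pten deletion the 3' set was 0.999 higher than in wild-type, by 0.84 or more between any 2 arrays. The mean 5' to 3' difference moved by 0.0075 there, so the rise of that set came without a shift in the mean of this measure. Its SD among the Pten deletion arrays was 0.25, and the marks for this test were set after the values were seen. Integrity is therefore not excluded for Pten deletion. With each array centred on the median of this table the set lay 0.30 and 0.52 below wild-type in Pten and Pten-Lrf deletion, so it rose less than the table as a whole. For the values in Pten-Lrf deletion integrity stays open as well. The 5' to 3' difference itself was 0.42 higher in Pten-Lrf deletion than in Pten deletion, at -0.43 against -0.85. The 5' signal thus lay less far below the 3' signal in Pten-Lrf deletion. The exact permutation p was 0.1, the smallest that 3 against 3 arrays allow, and all 3 Pten-Lrf deletion arrays lay above the other 6. A biological rise of Gapdh, a glycolysis gene, with genotype stays open and was not tested apart from the array values.

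Most genes of the table were higher in Pten-Lrf deletion than in Pten deletion, 1768 of 2173. The tilt lay against Pten deletion arrays 2 and 3, where 76.1% and 90.5% of genes were below the Pten-Lrf deletion mean, and not against array 1, with 49.8%. It turned to 887 higher and 1285 lower after quantile normalisation of the table, and to 813 and 1360 with each array centred. The row selection could give such a tilt. Among the 1646 genes at least 1.5-fold above wild-type in both deletion groups, 75.4% were still higher in Pten-Lrf deletion. The share was 64.2% or more with any Pten deletion array left out. Genes of an array can shift together, and the tilt was absent against array 1, so these shares do not decide on a rule on fold change alone. In limma fits of 2 groups Pten-Lrf deletion against wild-type had no p over 0.043, so a rule on p as well could have been in use. Among the 1531 genes that meet both the fold change and this p in each deletion group, the share was 73.6%, and 60.2% at the lowest with a Pten deletion array left out. The margin of this last share over the mark of 60% is narrow. That mark, used for both rules, was set after the data were seen, so neither rule is excluded as the whole cause. The selection rule is stated nowhere, and others stay open as well. RNA integrity and genotype cannot be told apart for this tilt, because the difference in integrity runs with Lrf loss: with the Gapdh difference as a covariate the median over genes went from 0.29 to 0.062. Mia stayed 4.34 higher with the covariate (SE 0.39), so integrity as it moved Mia within genotypes does not account for the rise. The covariate does not overlap between Pten-Lrf deletion and the other genotypes, so it cannot exclude integrity for Mia either. Effects of Lrf loss on many genes remain an open explanation of the tilt.

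The 3 Pten deletion arrays spread more than the others. An array-wide scaling does not account for it, since between arrays 2 and 1 the fibroblast and interferon lists moved apart by 3.45 log2 units, with all 11 fibroblast genes higher in array 2 and all 14 interferon genes lower. Pten deletion 1 had a table-wide level near that of Pten-Lrf deletion, which raises the question of a Pten-Lrf deletion sample under its label. Mia was at 6.54 there and at least 10.62 in each Pten-Lrf deletion array. Mia was taken after it was seen to separate the labelled groups, so it cannot exclude a wrong label. More stromal and macrophage RNA in array 2 may account for a part: both lists were higher there than in arrays 1 and 3, the smallest of the 4 median differences being 0.70, although 4 of the 14 macrophage genes were lower than in array 1. Lesions that differ between Pten deletion mice remain an untested explanation.

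The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. In Pten deletion against wild-type 1 split, the real one, gave as many genes as observed, 1743, and the highest other split gave 0. In Pten-Lrf deletion against Pten deletion 1 split gave 50 and the highest other 0, and in Pten-Lrf deletion against wild-type 1 split gave 2173 and the highest other 0.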

How the results depend on the processing

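The fit on rows selected alike for both deletion groups and the Gapdh covariate were chosen after the data were seen; all other alternatives were planned. Over the named genes, 2244 results under an alternative kept direction and side of the threshold, 124 no longer passed, 3 newly passed and 32 changed sign; for gene lists the numbers were 127, 22, 0 and 1. Of the 50 genes called in Pten-Lrf deletion against Pten deletion, 6 were called with every array left out in turn, against 1409 in Pten deletion against wild-type and 1995 in Pten-Lrf deletion against wild-type.

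The number of genes changed in Pten-Lrf deletion against Pten deletion, 50, was 27 after quantile normalisation, 13 after centring, 4 with the dimmest 0.25 of genes left out, 5 with only the 2 genotypes in the fit, 1072 with array weights, 6 at an adjusted p under 0.01, 13 on rows selected alike and 2 with the Gapdh covariate, under which all 50 genes kept their direction, 42 kept at least 50% of their log2 fold change, and the SE was at the median 140% of that without it. Leaving out 1 array gave 9 to 884: 884 without Pten deletion 1, 21 without Pten deletion 2, 12 without Pten deletion 3, 11, 9 and 10 without wild-type 1, 2 and 3, and 9, 10 and 14 without Pten-Lrf deletion 1, 2 and 3. The cause was not tested, except that the array weights gave Pten deletion 1 and 2 the lowest weights, 0.12 and 0.20, and the dim filter and the fit with 2 genotypes use fewer genes or arrays.

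The number for Pten deletion against wild-type, 1743, was 2812 with probe sets tested one by one and 1090 with a log2 fold change of at least 1, and 1483 to 1927 with 1 array left out. For Pten-Lrf deletion against wild-type, 2173, it was 1397 after quantile normalisation, 1405 after centring, 3521 with probe sets one by one, 1412 with a log2 fold change of at least 1, 1413 with the Gapdh covariate, and 2069 to 2173 with 1 array left out. Their overlap, 1743, was 1057 after quantile normalisation, 1069 after centring, 2811 with probe sets one by one and 1044 with a log2 fold change of at least 1. Testing more probe sets than genes, or asking for a minimum fold change, moves a count by construction; for the covariate the cause was not tested.

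Centring and quantile normalisation took away the table-wide rise: the median over genes went from 1.03 to -0.24 and -0.29 in Pten deletion against wild-type, from 0.29 to -0.11 and -0.08 in Pten-Lrf deletion against Pten deletion, and from 1.29 to -0.38 and -0.42 in Pten-Lrf deletion against wild-type. Centring by construction turned the sign of genes that rose less than the array medians over all probe sets. Some of them had risen more than the median over genes, such as Pdk1 at 1.61 in Pten-Lrf deletion against wild-type. After quantile normalisation genes above that median changed sign too, such as Mia at 1.55 in Pten deletion against wild-type, and the cause was not tested. In Pten deletion against wild-type, quantile normalisation and centring gave Bcl6 -0.094 and -0.12, Idi1 -0.51 and -0.47, and Scd1 -0.48 and -0.54, and quantile normalisation gave Mia -0.067. In Pten-Lrf deletion against Pten deletion they gave Sox9 -0.25 and -0.26 and Cdkn1a -0.12 and -0.23. In Pten-Lrf deletion against wild-type they gave Fkbp5 -0.44 and -0.52, Bcl6 -0.17 and -0.18, Cat -0.27 and -0.37, Pdk1 -0.0018 and -0.067, Idi1 -0.43 and -0.41, and Acly -0.46 and -0.51. There quantile normalisation alone gave Birc5 -0.19, Mcm5 -0.31 and Ccnb2 -0.49, and centring alone H2-Eb1 -0.013 and H2-Ab1 -0.087.

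Sox9 in Pten-Lrf deletion against Pten deletion, 0.14 and not past the threshold, was also below 0 with the mean of its probe sets (-0.016), array weights (-0.21), and with the Gapdh covariate (-0.42), and ran from -0.15 without Pten deletion 2 to 0.35 without Pten deletion 3. The interferon list, 0.22 below the other genes in that comparison, ran from -0.50 without Pten deletion 2 to 0.12, above them, without Pten deletion 1. Arrays of the same replicate number did not deviate together: r ran from -0.24 to 0.41 over 9 pairs, 2 of them over 0.1, and 3 of 9 arrays correlated best with their own number. A replicate block gave 41, 1729 and 2172 genes for Pten-Lrf deletion against Pten deletion, Pten deletion against wild-type and Pten-Lrf deletion against wild-type, with 30 of the 41 among the 50. No detection calls came with the values, so dim genes near a log2 value of 3 have no measured background.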

Other observations

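The genes of this paragraph and the next, all among the 49 rises in Pten-Lrf deletion against Pten deletion, were named after their values were seen. Upk1a, which encodes a uroplakin of the bladder surface, rose by 2.81 (SE 0.36), Cdh17, a cadherin of intestine, by 2.86 (SE 0.43), Tm4sf4 by 2.72 (SE 0.46), Lgals2 by 2.12 (SE 0.42) and the trefoil factor gene Tff1 by 1.27 (SE 0.21). Tff1 was not higher in Pten deletion than in wild-type, with means of 5.98 and 6.39, and reached 7.26 in Pten-Lrf deletion. Dmkn rose by 3.12 (SE 0.60), Csta1 by 2.32 (SE 0.40) and the ceramide synthase gene Cers3 by 1.66 (SE 0.34). Of these genes Upk1a is the 1 that was called with every array left out in turn.

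Saa1 and Saa2, the serum amyloid A genes, had risen with Pten deletion by 3.76 and 4.47 and rose further by 1.85 (SE 0.35) and 2.05 (SE 0.36). Serpina1b, an alpha-1-antitrypsin gene, stood at 3.30 in wild-type and 3.37 in Pten deletion and reached 6.52 ± 1.5 in Pten-Lrf deletion. Apoc1 went from 5.77 ± 0.24 to 7.93 ± 0.13, a rise of 2.16 (SE 0.21), and was called with every array left out in turn; the other genes of this paragraph were called in 1 or 2 of these 9 fits. Notch3 and Nrarp, a Notch target gene, rose by 1.27 (SE 0.22) and 1.65 (SE 0.31) over Pten deletion.

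Lists of textbook genes that left out the genes already seen were written before the tests of 3 hypotheses on Pten-Lrf deletion against Pten deletion, and none was borne out. A wider gut-type programme may lie behind the rises: of 80 listed gastrointestinal epithelial genes 12 were in the table and 11 had higher means, with Gpa33 2.17 higher (SE 0.56), but the median of 0.43 was only 0.14 above that of all genes (camera p = 0.449, and p = 0.774 with an estimated correlation). All 12 had risen with Pten deletion, at a median of 3.77. The Car9 rise may reflect hypoxia, but the 6 measured of 27 other hypoxia-inducible genes had a median 0.013 below that of all genes, well within their quartiles of 0.16 and 0.74. For that list camera gave p = 0.848, and p = 0.906 with an estimated correlation. Squamous differentiation may lie behind Ivl and Dmkn: 8 of 33 listed genes were in the table, 7 had higher means, and their median was 0.11 above that of all genes. Here camera gave p = 0.975, and p = 0.981 with an estimated correlation. None of the genes in these lists passed over all genes, and none is in another fixed list. The rule written before the tests counted a list median at or below that of all genes against a hypothesis, and the hypoxia list met it. The rule then applied asked for the third quartile of a list to lie below that median, which no list showed. On this changed rule, with 6 to 12 members in the table and spreads that include the median of all genes, all 3 hypotheses stay undecided.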
